A study of Mus musculus with 25 samples.

How the data were processed

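Full-length 16S rRNA gene amplicons were sequenced on a PacBio instrument from the feces of C57BL/6 mice in 5 groups of 5 libraries. The groups were named Sham, OVX, OVX+GEX, OVX+PBS and OVX+FMT by the labels. OVX is the usual abbreviation of ovariectomy and FMT of fecal microbiota transplantation, and PBS is a buffered saline used as vehicle. The design text speaks of estrogen deficiency and a traditional medicine, and GEX was left as written because the labels do not spell it out. The sex field of every sample reads male, which is at odds with ovariectomy, and the sex of the mice is therefore not stated here. Stool DNA was extracted with a commercial fecal DNA kit and made into hairpin-capped long-read libraries, per the labels' protocols.

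The deposited table held read counts per amplicon sequence variant (ASV, a distinct amplicon sequence after error removal) with a taxonomy of 7 ranks, per the file headers. It was converted from a BIOM file by the authors. Subread is listed in the submitters' processing notes with no version and no role. The denoiser, primers, taxonomy database and filters are not given in the sources used here. The counts were whole numbers, and 0 of the values above 0 were 1 while 464 were 2, and how values of 1 came to be missing is not given. Columns were matched to samples by name. The groups stand in another order in the table than in the numbered library names of the labels, and a match by order, which would give other groups to the OVX, OVX+GEX and OVX+PBS columns, was not used because the columns carry group names. Of the 25 columns, 5 were spelled OVX+GES where the titles read OVX+GEX, and they were taken as the OVX+GEX samples on the strength of the otherwise identical name and number. No other column was unmapped.

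The table held 1555 ASVs in 110 named genera, 37 families and 8 phyla, with 300831 counts in all. Library totals ran from 8498 to 22404 with a median of 10123. A count of 0 in a library allows a share of up to 3 counts of its total, and intervals and floors cover counting error only. Of the ASVs, 608 (39.1%) were seen in 1 library and held 1.61% of all counts. A single ASV with 13 counts had no phylum; it stayed in the library totals and diversity measures. Species names were given for 1554 ASVs. Genus and species names are names of relatives in an unstated database, and whether counts named Shigella belong to Escherichia was not tested.

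Counts were summed per genus and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) after TMM normalization, with all 25 libraries in 1 fit. Genera with a count of at least 3 in at least 5 libraries were kept, which left 81 genera, and the same rule left 379 ASVs for the ASV test. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Standard errors of log2 fold changes were taken from the F statistic. ASV richness was the expected number of ASVs in 8498 reads, computed analytically, and the Shannon index used natural logarithms of unrarefied shares. Community differences were PERMANOVA R2 values on Bray-Curtis distances of ASV shares. These measures, the shares of phyla, of the 5 most abundant genera and of taxon lists were compared by exact two-sided permutation tests over all splits of 10 libraries into 5 and 5, so that the smallest p was 0.00794. Adjustment was over the 4 comparisons for each community measure and within a comparison for shares. Labels say that the samples are separate but nothing about cages, litters or days, so p-values measure the spread between these libraries. No libraries were duplicates: the smallest Bray-Curtis distance within a group was 0.300, against at most 0.108 from sampling noise.

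The taxa to be named were set before the data were examined: phyla with a mean share of at least 1%, up to 10 genera each way past the threshold, the 5 most abundant genera, list members past the threshold, and up to 3 ASVs each way past it. Any further genus or ASV was chosen after its values were seen. There were 14 taxon lists, set at the same time: genera with members known to carry genes for forming trimethylamine (trimethylamine-forming genera below), butyrate producers, lactic acid bacteria with bifidobacteria, mucus-associated genera, Muribaculaceae, Lachnospiraceae, Oscillospiraceae with Ruminococcaceae, Rikenellaceae with Prevotellaceae and Bacteroidaceae, Enterobacterales, Erysipelotrichaceae, sulfate reducers, segmented filamentous bacteria, reagent contaminants and unplaced reads. The sulfate reducers, segmented filamentous bacteria and reagent contaminants had no counts, which left 11 lists. The lists go by genus or family name, and a share of 16S counts does not show that the bacteria present carry the genes or form the product.

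Alternatives were TMMwsp, size factors of DESeq2 1.42.0, plain totals, DESeq2's Wald test, limma 3.58.1 on centred log-ratios with 0.5 added to each count, other filters, only the groups compared, the replicate number as a block, each library left out, other diversity indices and distances, and a log scale for shares with 0.01% added. The tests were tried on simulated data first. In 40 simulations of OVX against Sham on 81 genera with 20 changed, edgeR recovered 18.5% of 4-fold and 59.5% of 16-fold changes, and 4.9% of its calls were false. In 20 simulations on 379 ASVs with 200 changed, it recovered 0.80% of 4-fold and 7.1% of 16-fold changes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.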

Results

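The fecal bacteria of 25 libraries were profiled, 5 in each of the groups Sham, OVX, OVX+GEX, OVX+PBS and OVX+FMT. Totals were 9735 to 22404 counts per library in Sham, 9189 to 11252 in OVX, 8498 to 10771 in OVX+GEX, 8558 to 21751 in OVX+PBS and 9484 to 22403 in OVX+FMT. Firmicutes held 1464 of the 1555 ASVs. The 5 genera with the highest mean share were Duncaniella, an anaerobe of the Muribaculaceae; Ligilactobacillus, a lactic acid bacterium; and Ruminococcus, Acetivibrio and Anaerobacterium, clostridia of which the first 2 are known for degrading plant fibre.

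Whether the OVX community differed from that of Sham was asked first. ASV richness fell in OVX. The expected number of ASVs in 8498 reads was 358 ± 35.1 in Sham and 252.3 ± 39.2 in OVX (SD, n = 5), with all OVX libraries below all Sham libraries (exact permutation p = 0.00794, the smallest the splits allow; adjusted p = 0.0317 over 4 comparisons). Duncaniella took 13.2% ± 5.91 of the counts in Sham and 23.3% ± 13.1 in OVX, and Ligilactobacillus 11.9% ± 6.37 and 24.8% ± 12.6 (SD, n = 5), with adjusted exact p-values of 0.198 for both over 5 genera. Acetivibrio averaged 8.11% ± 1.96 in Sham and 3.97% ± 1.87 in OVX, and all 5 OVX libraries lay below the Sham median (exact permutation p = 0.0159, adjusted p = 0.0794). Ruminococcus (5.50% and 6.34%) and Anaerobacterium (6.33% and 4.72%) differed by less than their spread.

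**Figure D1:**
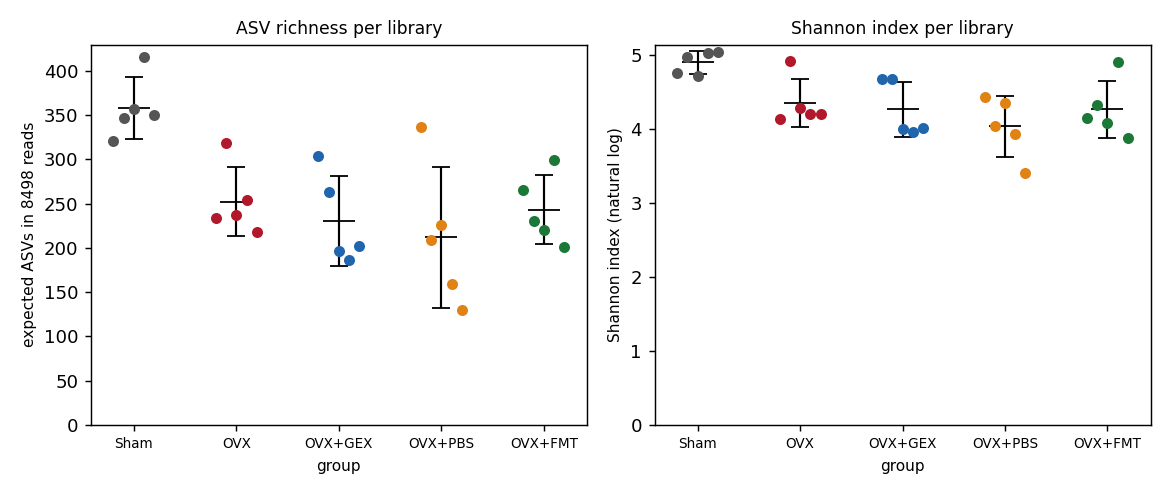
ASV richness (expected ASVs in 8498 reads, left) and Shannon index (right) on the y axes against group on the x axis; each point is a library, the bar is the group mean and the whiskers are 1 SD. The 5 Sham libraries lie between 320 and 416 expected ASVs, above all 5 OVX libraries.

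Among phyla, Firmicutes held 80.8% ± 6.73 of Sham and 71.8% ± 12.6 of OVX counts, Bacteroidetes 14.8% ± 7.03 and 24.7% ± 13.3, and Verrucomicrobia 3.34% ± 2.64 and 2.24% ± 1.72 (SD, n = 5), with adjusted exact p-values of 0.508, 0.508 and 0.762. The log2 ratio of Firmicutes to Bacteroidetes was 2.54 ± 0.67 in Sham and 1.66 ± 0.97 in OVX (exact permutation p = 0.127); without Sham replicate 1 the difference was -1.17 with an exact p of 0.0238, and without OVX replicate 2 it was -1.14 with an exact p of 0.0476, while without OVX replicate 1 it was -0.49 with an exact p of 0.262. None of the 11 lists passed adjustment. Lachnospiraceae, a family with many short-chain fatty acid producers, averaged 33.4% ± 8.71 in Sham and 18.5% ± 11.7 in OVX (exact permutation p = 0.0635, adjusted p = 0.320), and Oscillospiraceae with Ruminococcaceae 24.2% ± 1.85 and 18.1% ± 4.21 (exact permutation p = 0.0238, adjusted p = 0.262). Genera with members known to form trimethylamine, the precursor of the trimethylamine oxide named in the study's title, held 8.84% ± 3.67 and 4.80% ± 5.01 (adjusted exact p = 0.364); whether the bacteria present carried the genes was not measured. The OVX mean rested on OVX replicate 2, at 13.6%: the other 4 OVX libraries held 1.34% to 4.24%, below the lowest Sham library (5.84%), and without it the difference was -6.23 points (adjusted exact p = 0.105). Without the same library Lachnospiraceae differed by -19.9 points and butyrate producers by -7.87 (adjusted exact p = 0.105 for both). Butyrate producers held 14.7% ± 6.60 and 8.99% ± 5.55, and lactic acid bacteria with bifidobacteria 12.04% ± 6.51 and 25.4% ± 13.0 (adjusted exact p of 0.364 and 0.320). Mucus-associated genera, Muribaculaceae (here Duncaniella alone), Bacteroidaceae with relatives (here Bacteroides alone), Enterobacterales, Erysipelotrichaceae and unplaced reads had adjusted exact p-values of 0.327 to 1.0.

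At the genus level edgeR's quasi-likelihood test placed 0 of 81 genera past the threshold for OVX against Sham, with 9 at an unadjusted p under 0.05, 1 past it by DESeq2 and 1 by limma on centred log-ratios. No list had a member past the threshold, over all genera or adjusted over the list alone. Of 23 Lachnospiraceae genera tested 8 had a higher and 15 a lower estimate in OVX, and of 18 Oscillospiraceae and Ruminococcaceae 8 and 10. The limma call was Haploplasma, a wall-less bacterium of the Tenericutes, named after its values were seen: it had 0 counts in all 5 Sham libraries and counts in 4 of 5 OVX libraries, at least 4.05-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.225, limma adjusted p = 0.000837, 0.000837 to 0.424 over the alternatives). The DESeq2 call, Shigella (adjusted p = 0.0028), was also named after its values were seen and rested on 3 counts in OVX replicate 4. Lawsonibacter, a Firmicutes genus also chosen after its values were seen, averaged 0.333% ± 0.201 in Sham and 1.11% ± 0.586 in OVX, a log2 fold change of 2.19 (SE 0.73, edgeR adjusted p = 0.225). With plain totals in place of TMM, the median log2 fold change over genera moved from 0.15 to -0.22; it moved from 0.13 to -0.03 for OVX+GEX against OVX and from -0.47 to -0.66 for OVX+PBS against OVX, so directions of genera without a call depend on the scaling.

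The Shannon index was 4.91 ± 0.156 in Sham and 4.35 ± 0.324 in OVX (SD, n = 5; exact permutation p = 0.0238, adjusted p = 0.0952). The grouping took R2 = 0.220 of the Bray-Curtis variation (exact permutation p = 0.0238, adjusted p = 0.0952), and R2 was 0.218 without Sham replicate 4 and 0.219 without Sham replicate 5, each with an exact p of 0.0556, and 0.278 without OVX replicate 2 (exact permutation p = 0.00794). Both the Shannon and the R2 comparison thus passed 0.05 only before adjustment.

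**Figure D2:**
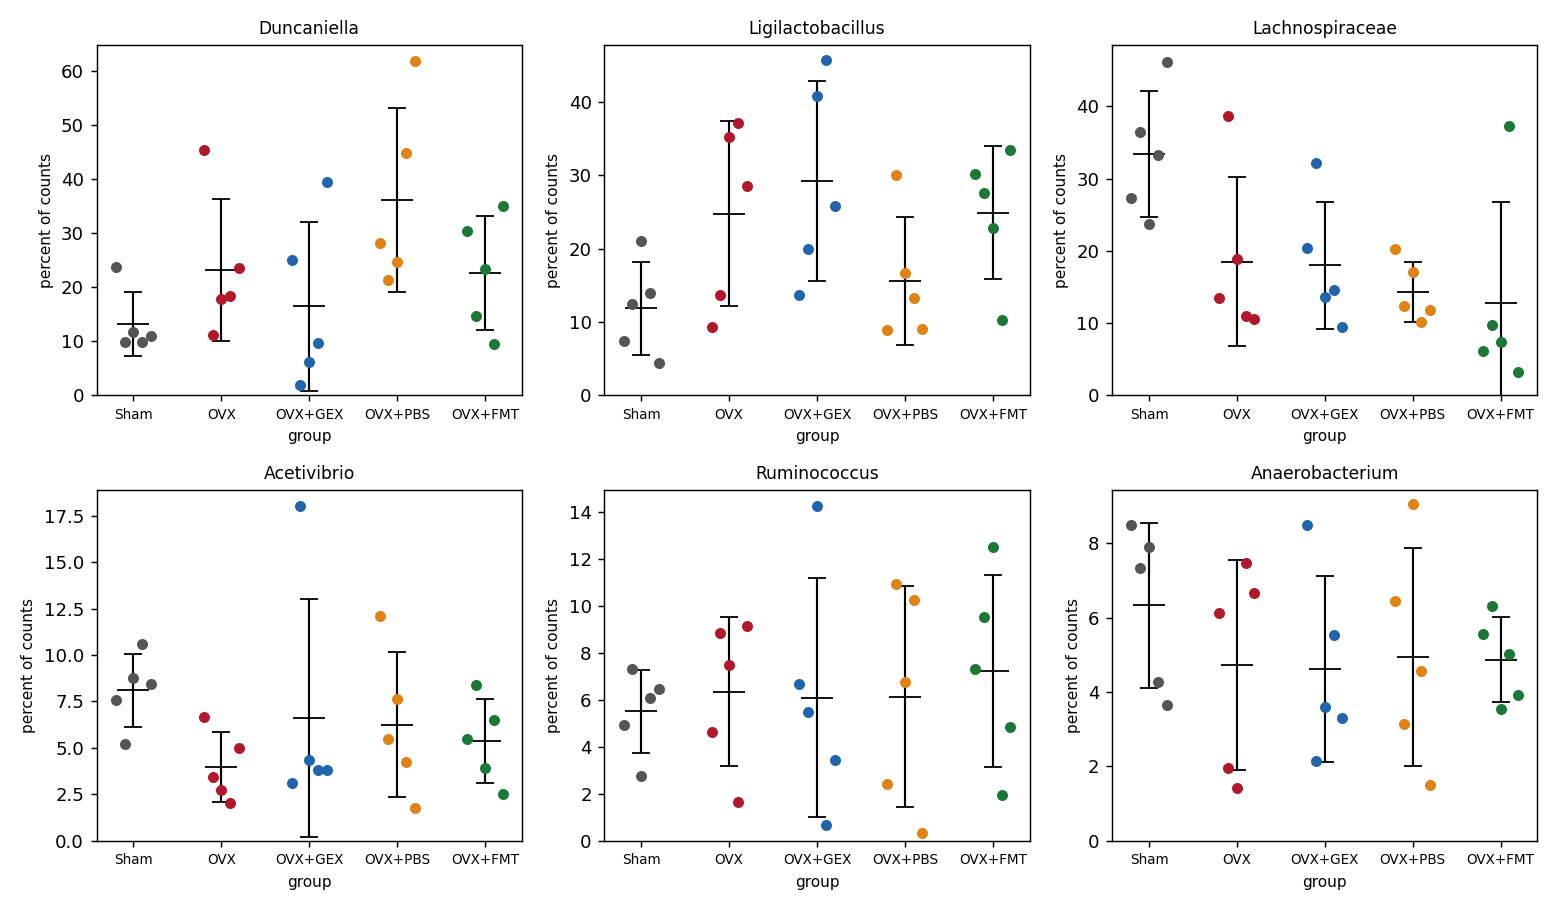
Share of counts (percent, y axes) of Duncaniella, Ligilactobacillus, the family Lachnospiraceae, Acetivibrio, Ruminococcus and Anaerobacterium against group (x axes); points are libraries, bars are means and whiskers 1 SD, of which the lower one for Lachnospiraceae in OVX+FMT runs below 0. Lachnospiraceae reached 37.3% in OVX+FMT replicate 4 and lay between 3.29% and 9.78% in the other 4 OVX+FMT libraries.

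The second comparison asked whether the community of OVX mice given GEX differed from that of OVX mice. ASV richness was 231 ± 51.1 in OVX+GEX and 252.3 ± 39.2 in OVX (SD, n = 5; exact permutation p = 0.444), and the Shannon index 4.27 ± 0.374 and 4.35 ± 0.324 (exact permutation p = 0.794). Ligilactobacillus averaged 29.2% ± 13.6 in OVX+GEX and 24.8% ± 12.6 in OVX, Duncaniella 16.5% ± 15.6 and 23.3% ± 13.1, Acetivibrio 6.61% ± 6.38 and 3.97% ± 1.87, Ruminococcus 6.09% ± 5.09 and 6.34% ± 3.17, and Anaerobacterium 4.61% ± 2.49 and 4.72% ± 2.82; each had an adjusted exact p of 0.960. Firmicutes held 77.1% ± 16.5 against 71.8% ± 12.6, Bacteroidetes 18.1% ± 16.9 against 24.7% ± 13.3 and Verrucomicrobia 2.33% ± 1.22 against 2.24% ± 1.72, with adjusted exact p-values of 0.927, 0.927 and 0.944. The Firmicutes to Bacteroidetes log2 ratio was 2.76 ± 2.08 and 1.66 ± 0.97 (exact permutation p = 0.333).

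Trimethylamine-forming genera held 5.48% ± 4.44 in OVX+GEX and 4.80% ± 5.01 in OVX, butyrate producers 8.03% ± 2.97 and 8.99% ± 5.55, and Lachnospiraceae 18.04% ± 8.79 and 18.5% ± 11.7. The 11 lists had adjusted exact p-values of 0.899 to 0.937. Enterobacterales, the order of Escherichia and Shigella, averaged 1.09% ± 2.35 in OVX+GEX and 0.00593% ± 0.0132 in OVX, because OVX+GEX replicate 4 alone held 450 such counts, 5.30% of its total (Wilson 95% interval 4.84% to 5.79%).

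For OVX+GEX against OVX, edgeR's quasi-likelihood test placed 0 of 81 genera past the threshold, with 5 at an unadjusted p under 0.05, 0 past it by DESeq2 and 1 by limma on centred log-ratios. The limma call was Haploplasma again, chosen after its values were seen, with 0 counts in all 5 OVX+GEX libraries, at least 3.18-fold lower than in OVX (edgeR adjusted p = 0.216, limma adjusted p = 0.0234, up to 0.562 over the alternatives). It also had 0 counts in all 5 OVX+PBS libraries and in 4 of 5 OVX+FMT libraries, so its absence was not particular to GEX. Adjusted over the list alone, Shigella passed among the Enterobacterales and among the trimethylamine-forming genera, and Lactobacillus (0.0689% ± 0.0677 in OVX+GEX and 0.550% ± 0.445 in OVX; log2 fold change -2.75, SE 1.01) among the lactic acid bacteria, with adjusted p-values over the list of 0.0056, 0.0333 and 0.0426 by edgeR. Shigella was the 1 Enterobacterales genus tested, so its edgeR p of 0.0056 there is unadjusted. Over all genera Shigella and Lactobacillus each had an edgeR adjusted p of 0.216. The Shigella counts came from OVX+GEX replicate 4 for the most part, and without it the edgeR adjusted p was 0.850. The grouping took R2 = 0.0909 of the Bray-Curtis variation (exact permutation p = 0.643).

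Next, OVX mice given a fecal transplant were set against OVX mice given PBS; the donors are not named in the labels. Duncaniella averaged 22.6% ± 10.6 in OVX+FMT and 36.2% ± 17.0 in OVX+PBS, Ligilactobacillus 24.9% ± 9.07 and 15.6% ± 8.71 (SD, n = 5; adjusted exact p = 0.437 for both), Ruminococcus 7.23% ± 4.08 and 6.14% ± 4.68, Acetivibrio 5.36% ± 2.27 and 6.25% ± 3.92, and Anaerobacterium 4.87% ± 1.15 and 4.93% ± 2.93 (adjusted exact p of 0.863, 0.863 and 0.968). Firmicutes held 69.4% ± 9.24 and 58.3% ± 17.8, Bacteroidetes 24.6% ± 11.2 and 39.0% ± 18.3, and Verrucomicrobia 4.26% ± 3.14 and 1.61% ± 1.03, with adjusted exact p-values of 0.50, 0.375 and 0.375. ASV richness was 243 ± 39.0 and 212 ± 79.5 (exact permutation p = 0.452), and the Shannon index 4.27 ± 0.389 and 4.04 ± 0.408 (exact permutation p = 0.413). The Firmicutes to Bacteroidetes log2 ratio was 1.63 ± 0.93 and 0.63 ± 1.15 (exact permutation p = 0.183), and R2 was 0.161 (exact permutation p = 0.151).

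For OVX+FMT against OVX+PBS, edgeR's quasi-likelihood test placed 0 of 81 genera past the threshold, with 12 at an unadjusted p under 0.05, 2 past it by DESeq2 and 1 by limma on centred log-ratios. Bifidobacterium, a fermenter of sugars chosen after its values were seen, had the smallest adjusted p. It held 19 to 66 counts in 4 OVX+FMT libraries, 0 in OVX+FMT replicate 4 and 0 in all 5 OVX+PBS libraries, at least 9.27-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.0812, limma adjusted p = 0.0169, up to 0.113 over the alternatives). Without OVX+FMT replicate 4, edgeR called 2 genera, Bifidobacterium and Marvinbryantia (adjusted p = 0.0120 for both). Marvinbryantia had 0 counts in those 4 OVX+FMT libraries and 0 to 25 in the OVX+PBS libraries, and no fold is given. DESeq2 called 2 genera, like Marvinbryantia named after their values were seen: Gluceribacter (log2 fold change -1.43) and Ihubacter (log2 fold change -1.57), each with an adjusted p of 0.0426 (up to 0.434 and 0.388 over the alternatives).

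Adjusted over the list alone, 2 lactic acid bacteria and bifidobacteria passed by edgeR, Bifidobacterium and Lactococcus. Lactococcus had 0 counts in OVX+PBS and a mean of 0.0260% in OVX+FMT, which is under the OVX+PBS floor of 0.0287%, so no fold is given. Their list as a whole held 25.6% ± 9.28 in OVX+FMT and 16.3% ± 9.23 in OVX+PBS (adjusted exact p = 0.480). Trimethylamine-forming genera held 2.06% ± 3.24 and 1.91% ± 0.987, butyrate producers 6.40% ± 7.48 and 6.27% ± 2.69, and Lachnospiraceae 12.8% ± 13.9 and 14.3% ± 4.20, each with an adjusted exact p of 1.0. These 3 OVX+FMT means rested on OVX+FMT replicate 4. Without it Lachnospiraceae differed by -7.69 points, with the other 4 OVX+FMT libraries (3.29% to 9.78%) all below the lowest OVX+PBS library (10.2%; adjusted exact p = 0.0873), and trimethylamine-forming genera and butyrate producers differed by -1.29 and -3.18 points (adjusted exact p = 0.157 for both). Erysipelotrichaceae averaged 1.14% ± 0.556 and 0.418% ± 0.150 (exact permutation p = 0.0317, adjusted p = 0.349). The mucus-associated genera, which include the mucin degrader Akkermansia, held 5.87% ± 2.78 and 3.89% ± 0.742 (adjusted exact p = 0.480), and the remaining 5 lists had adjusted exact p-values of 0.480 to 1.0. OVX+FMT replicate 4 stood apart within its group: 7.83% trimethylamine-forming genera and 19.7% butyrate producers, against at most 0.996% and 4.56% in the other 4 libraries.

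OVX+PBS was also set against OVX, to see whether the vehicle group differed from the group without one. Duncaniella averaged 36.2% ± 17.0 in OVX+PBS and 23.3% ± 13.1 in OVX, and Ligilactobacillus 15.6% ± 8.71 and 24.8% ± 12.6 (SD, n = 5; adjusted exact p = 0.476 for both). Acetivibrio, Ruminococcus and Anaerobacterium had adjusted exact p-values of 0.476, 0.937 and 0.937. Firmicutes held 58.3% ± 17.8 and 71.8% ± 12.6, Bacteroidetes 39.0% ± 18.3 and 24.7% ± 13.3 and Verrucomicrobia 1.61% ± 1.03 and 2.24% ± 1.72, with adjusted exact p-values of 0.529, 0.529 and 0.608. Bacteroidaceae with relatives, here Bacteroides alone, averaged 2.22% ± 0.973 and 1.03% ± 0.471 (exact permutation p = 0.0238, adjusted p = 0.262). The other 10 lists had adjusted exact p-values of 0.524 to 0.738.

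EdgeR's quasi-likelihood test placed 0 of 81 genera past the threshold for OVX+PBS against OVX, with 11 at an unadjusted p under 0.05, 1 past it by DESeq2 and 0 by limma on centred log-ratios. The DESeq2 call was Gluceribacter, chosen after its values were seen (6.62% ± 2.66 in OVX+PBS and 2.79% ± 1.06 in OVX; edgeR log2 fold change 1.60, SE 0.50, adjusted p = 0.162; DESeq2 adjusted p = 0.0031, up to 0.300 over the alternatives). Haploplasma, chosen after its values were seen, had 0 counts in all 5 OVX+PBS libraries, at least 3.43-fold lower than in OVX (edgeR adjusted p = 0.162). Shigella, the 1 Enterobacterales genus tested, had a p of 0.0154 adjusted over the list alone and of 0.207 over all genera; without OVX+PBS replicate 5 the latter was 0.579. ASV richness was 212 ± 79.5 and 252.3 ± 39.2 (exact permutation p = 0.325), and without OVX+PBS replicate 1 it was lower by a mean difference of -71.4 (exact permutation p = 0.0238), but without OVX+PBS replicate 5 by -19.7 (exact permutation p = 0.603). R2 was 0.161 (exact permutation p = 0.143) and 0.245 without OVX replicate 1 (exact permutation p = 0.0238), but 0.140 without OVX replicate 3 (exact permutation p = 0.317). The Shannon index differed by -0.314 (exact permutation p = 0.246), and the Firmicutes to Bacteroidetes log2 ratio by -1.03 (exact permutation p = 0.159), with -1.42 without OVX replicate 1 (exact permutation p = 0.0476) and -0.60 without OVX+PBS replicate 5 (exact permutation p = 0.325).

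**Figure D3:**
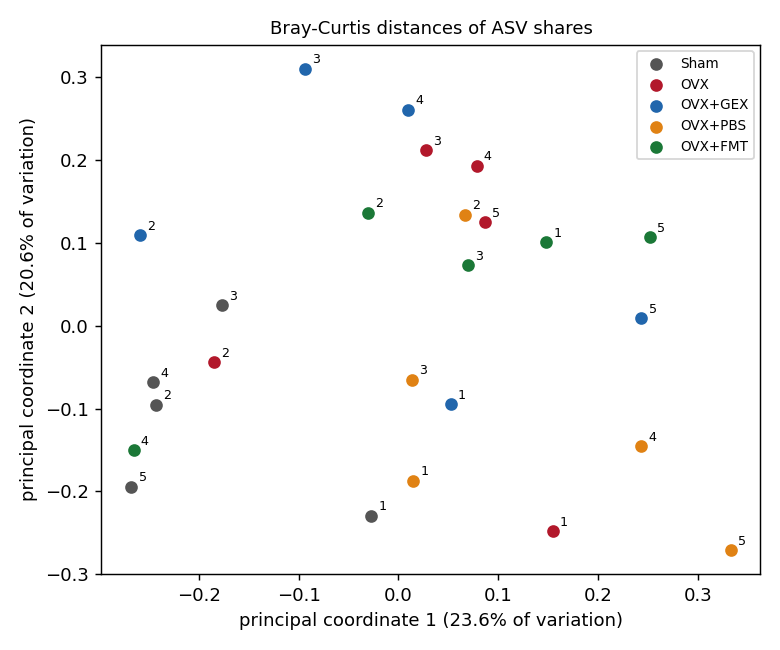
Principal coordinates of Bray-Curtis distances between ASV shares; axis 1 (x) holds 23.6% and axis 2 (y) 20.6% of the variation, each point is a library numbered by replicate and colours are groups. OVX+FMT replicate 4 and OVX replicate 2 lie on the left at axis 1 values of -0.265 and -0.185, beside 4 of the Sham libraries and OVX+GEX replicate 2.

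Whether GEX or the transplant brought libraries nearer to Sham was asked of the distances. The mean Bray-Curtis distance to the Sham libraries was 0.569 ± 0.0411 for OVX+GEX and 0.548 ± 0.0208 for OVX (SD, n = 5; exact permutation p = 0.333); without OVX+GEX replicate 1 the difference was 0.0380, OVX+GEX being farther (exact permutation p = 0.0159), and without OVX+GEX replicate 4 it was 0.0097 (exact permutation p = 0.627). It was 0.534 ± 0.0438 for OVX+FMT and 0.551 ± 0.0862 for OVX+PBS (exact permutation p = 0.722). The distance to the OVX+GEX libraries was 0.490 ± 0.0738 for OVX+FMT and 0.528 ± 0.0839 for OVX+PBS (exact permutation p = 0.460).

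Genera reversed by GEX, past the threshold in OVX against Sham and past it the other way in OVX+GEX against OVX, numbered 0 by edgeR. That 0 was fixed in advance, since edgeR called 0 genera in both comparisons, with 9 and 5 at an unadjusted p under 0.05. The count of reversed genera was 1 by limma on centred log-ratios, Haploplasma, which was as absent from OVX+PBS as from OVX+GEX. Both comparisons use the OVX libraries, so opposite signs arise with no effect: the log2 fold changes of the 81 genera correlated at r = -0.375 across genera, which are not independent replicates, and 40 simulations with no effect gave a mean of -0.510. Their covariance was -1.22 against a simulated -1.21. The simulated count of reversed genera was 0, and so, by construction, was the product of both counts over the genera tested. The GEX effect differed from the FMT effect in 0 of 81 genera by edgeR, with 9 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma on centred log-ratios; with no filter on low counts, 1 genus passed, Shigella, named after its values were seen.

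Below the genus level, edgeR's quasi-likelihood test on 379 ASVs called 0 for OVX against Sham, 0 for OVX+GEX against OVX and 0 for OVX+FMT against OVX+PBS. At an unadjusted p under 0.05 there were 65, 73 and 80 ASVs, and other splits of the same libraries gave medians of 44, 67 and 63 and highest counts of 58, 96 and 94. The 65 ASVs of OVX against Sham thus exceeded every other split drawn, while none of them passed adjustment, and the counts of the other comparisons did not. DESeq2 called 2, 2 and 5 ASVs, and limma on centred log-ratios 1, 0 and 0. Among the DESeq2 calls, chosen after their values were seen, was ASV_70, assigned to Ligilactobacillus murinus, which was present in 4 of 5 OVX+FMT and 0 of 5 OVX+PBS libraries (edgeR adjusted p = 0.0661, DESeq2 adjusted p = 0.000492, up to 0.165 over the alternatives). Without OVX+FMT replicate 4 edgeR called ASV_70 too (adjusted p = 0.0421).

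OVX+PBS against OVX was run per ASV only after the data were seen. EdgeR called 0 of 379 ASVs, with 94 at an unadjusted p under 0.05, of which 23 were higher and 71 lower in OVX+PBS. Other splits of these libraries gave a median of 70 and at most 95, and 2 of 100 splits, the real one included, gave at least 94. DESeq2 called 5 ASVs and limma on centred log-ratios 0. The smallest edgeR adjusted p, 0.0659, was shared by ASV_70 and ASV_80, both chosen after their values were seen. Each had 0 counts in all 5 OVX+PBS libraries, and they were seen in 5 and 4 of 5 OVX libraries, at least 11.1-fold and 22.0-fold lower in OVX+PBS against a floor of 3 counts per library (adjusted p up to 0.112 over the alternatives for both).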

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

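Chosen only after the result was seen were the tests of depth, outside DNA and a wrong label for OVX+FMT replicate 4, the ASV-level tests of the difference of effects and of OVX+PBS against OVX, and the counts over other splits except those for the ASV-level difference and for the 4 OVX groups against Sham.

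Lachnospiraceae, trimethylamine-forming genera and butyrate producers set 1 OVX+FMT library apart. In OVX+FMT replicate 4 they held 37.3%, 7.83% and 19.7% of the counts, against 3.29% to 9.78%, 0.314% to 0.996% and 2.04% to 4.56% in the other 4 OVX+FMT libraries. Its distance to the OVX+GEX libraries, 0.618, lay beyond the 0.435 to 0.484 of those 4. The library also had 0 counts of Bifidobacterium.

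Its mean Bray-Curtis distance to the other 4 OVX+FMT libraries was 0.593 ± 0.0784, against 0.354 ± 0.0516 among those 4. The tables argue against depth, since after subsampling to the smallest total the distance was 0.594, and against DNA from outside the gut as the whole cause, since ASVs seen in this library alone held 1.39% of its counts and the distance without them was 0.590. Legionella (2 counts), Gloeocapsopsis (4) and Persicirhabdus (4), chosen after their values were seen, occurred in this library alone of 25, so a small part from outside is not excluded. A wrong label may account for it: the group nearest to it was Sham, at a mean distance of 0.495 ± 0.0322, against 0.605 ± 0.0841 to OVX+PBS, 0.592 ± 0.0357 to OVX and 0.618 ± 0.0355 to OVX+GEX. Other values go against Sham as the true group without excluding it: 299 expected ASVs, where the Sham libraries had 320 to 416, and 6 counts of Haploplasma, where all 5 Sham libraries had 0. Outside this library Haploplasma was seen only in OVX, in 4 of 5 libraries, so OVX as the true group is not excluded either. A distance to Sham this small was also not particular to this library, being 0.469 and 0.489 in OVX+PBS replicates 3 and 1. An effect of the donor stays open as untested, since the labels name neither donors nor cages.

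Single libraries also lay far from their groups in other measures, as judged by the gap to the nearest library over the range of the group. Chance gives about 1 such library in 20 groups, or 5.2 in the 105 tested, and 18 were found. The tests are not separate, since many of the measures share the same counts: 5 of the 18 fell in Sham replicate 1 and 4 in OVX+FMT replicate 4. The excess over 5.2 is therefore no measure of how many libraries stood apart. In Sham replicate 1, Duncaniella held 23.7% (9.82% to 11.7% in the others), Bacteroidetes 27.4% (11% to 12.5%), Bacteroidaceae with relatives 2.82% (0.645% to 0.991%) and Erysipelotrichaceae 1.82% (0.652% to 0.893%), and the Firmicutes to Bacteroidetes log2 ratio was 1.36 (2.66 to 2.97). OVX replicate 2 had a Shannon index of 4.92 (4.14 to 4.29) and 13.6% trimethylamine-forming genera (1.34% to 4.24%). Bacteroidaceae with relatives held 1.84% in OVX replicate 1 (0.631% to 0.957% in the others) and 2.98% in OVX+FMT replicate 5 (0.970% to 1.34%). Oscillospiraceae with Ruminococcaceae held 5.13% in OVX+PBS replicate 5 (21.5% to 25.5%), and Acetivibrio 18% in OVX+GEX replicate 2 (3.09% to 4.35%). Enterobacterales held 5.30% in OVX+GEX replicate 4, 1.11% in OVX+PBS replicate 5 and 0.0296% in OVX replicate 4, the last resting on 3 counts, against at most 0.132%, 0.269% and 0 in the other libraries of each group. Wilson 95% intervals of these shares reached at most 0.973 points either side.

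The effects of GEX and of the transplant differed for 8 ASVs by edgeR's quasi-likelihood test of the difference, a test added after the data were seen. Each effect is taken against its own reference, OVX or OVX+PBS, so a difference between these references alone can yield a call. The 3 lowest adjusted p-values belonged to ASV_77, assigned to Eubacterium xylanophilum (0.0070), ASV_54, assigned to Kineothrix alysoides (0.0070), and ASV_80, assigned to Eubacterium coprostanoligenes (0.0075). ASV_77 had counts in 3 OVX and 3 OVX+FMT libraries and in no OVX+GEX or OVX+PBS library. ASV_54 had counts in 5 OVX+GEX and 3 OVX+PBS libraries, 1 OVX library and no OVX+FMT library. ASV_80 was also absent from OVX+PBS, so which groups drive these calls is not settled. Of 100 regroupings of these libraries, the real one included, 8 gave at least 8 ASVs and the highest gave 27, so chance cannot be excluded. The regroupings mixed OVX+GEX with OVX+FMT and OVX with OVX+PBS. They thus took both references as alike and do not test equal effects alone. The split with 27 leaves open a structure of the samples other than their groups, or ASVs that vary together, and neither was tested. Without 1 library the count was 2 (OVX+GEX replicate 2), 3 (OVX+PBS replicate 1 or 3), 4 (OVX replicate 1, 4 or 5, OVX+FMT replicate 1, 2 or 5), 5 (OVX+GEX replicate 1 or 3) or 13 (OVX+FMT replicate 3), with ASV_77 and ASV_80 among the calls each time.

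Where the count was 0, every split gave at least as many by construction, so the 100 of 100 splits say nothing about chance. That holds for the genus counts of OVX against Sham, OVX+GEX against OVX, OVX+FMT against OVX+PBS, OVX+PBS against OVX and the difference of effects, where the highest other split gave 0, 2, 5, 1 and 3 genera. It holds for the genera reversed by GEX, with 0 as the highest, and for the ASV counts of the first 4 comparisons, with 0, 4, 6 and 3 as the highest. At an unadjusted p under 0.05, OVX against Sham had 9 genera, where the highest other split had 11, and 65 ASVs, where the highest had 58. OVX+PBS against OVX had 94 ASVs, where the highest had 95.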

How the results depend on the processing

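Of 3279 values from alternatives, 3177 kept their side of the threshold, and their size where untested. Of these, 2712 of 2751 were named taxa with no call to begin with. Of the 3279, 0 were counted as reversed. In most tests a change of sign counted only where the main or the alternative value passed 0.05, so this 0 says little about directions. Results that answer a comparison kept 465 of 528, with 49 moved, 8 weaker and 6 stronger. The alternatives with libraries under 12000 counts, those for the 4 OVX groups together and those for the ASV-level difference of effects and the ASV-level OVX+PBS against OVX were chosen after seeing the data. The cause of a change was not tested unless stated. The replicate numbers were not taken as pairs, since in no comparison did all 5 same-numbered pairs correlate above 0.1: 1, 4, 2 and 0 did, in the order of the results, and 1, 3, 2 and 0 of 5 libraries correlated best with their own number. OVX+GEX against OVX came nearest, with correlations of 0.091 to 0.201 in its 5 pairs, so pairing is not excluded there. With the block this comparison gave 0 genera, 0 ASVs and -21.8 expected ASVs (exact p = 0.438). With the replicate number as a block, OVX against Sham gave -105.6 expected ASVs, a Shannon difference of -0.55 and R2 = 0.220, each with an exact p of 0.0625, the smallest a paired test of 5 allows, so no call could be made or kept in these tests. The ASVs differing between the effects numbered 4 with the block. The inverse Simpson index gave -26.4 for OVX against Sham (exact permutation p = 0.0714). In libraries under 12000 counts the Shannon difference was -0.58 and R2 0.253, each with an exact p of 0.0536 on 8 libraries, fewer than before.

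Genera past the threshold by DESeq2 numbered 1 for OVX against Sham, 2 for OVX+FMT against OVX+PBS and 1 for OVX+PBS against OVX. By limma on centred log-ratios there was 1 for each of OVX against Sham, OVX+GEX against OVX and OVX+FMT against OVX+PBS, and 1 reversed by GEX. With no filter there was 1 for each of OVX+GEX against OVX, OVX+FMT against OVX+PBS and the difference of effects. ASVs numbered 2, 2 and 5 by DESeq2 for OVX against Sham, OVX+GEX against OVX and OVX+FMT against OVX+PBS, 1 by limma for OVX against Sham, 1 with no filter for OVX against Sham and for OVX+GEX against OVX, and 2 with the compared groups alone for OVX+GEX against OVX and OVX+FMT against OVX+PBS. For OVX+PBS against OVX they numbered 2 with TMMwsp, 5 by DESeq2, 6 with no filter, 2 with the stricter filter and 4 with the compared groups alone. The 8 ASVs differing between the effects became 19 with TMMwsp, 17 with DESeq2's size factors, 5 by DESeq2 and 2 by limma. Genera differing between the 4 OVX groups and Sham, 1 by edgeR, numbered 7 with plain totals (1 higher, 6 lower) and 7 by limma (5 higher, 2 lower), with 1 shared with edgeR each time.

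Leaving out each library in turn gave 0 to 2 genera and 0 to 1 ASVs for OVX+FMT against OVX+PBS (both highest without OVX+FMT replicate 4), 0 to 1 ASVs for OVX+PBS against OVX (highest without OVX replicate 4), 2 to 13 ASVs differing between the effects (lowest without OVX+GEX replicate 2, highest without OVX+FMT replicate 3) and 0 to 3 genera for the 4 OVX groups (0 without Sham replicate 1, 2 or 5, 3 without Sham replicate 3). R2 ran from 0.199 to 0.278 for OVX against Sham and from 0.140 to 0.245 for OVX+PBS against OVX. The Firmicutes to Bacteroidetes log2 difference ran from -1.17 to -0.49 and from -1.42 to -0.60 for these comparisons, richness for OVX+PBS against OVX from -71.4 to -19.7, and the difference in distance to Sham for OVX+GEX against OVX from 0.0097 to 0.0380. Simulations of OVX against Sham at this depth and group size recovered 18.5% of 4-fold and 59.5% of 16-fold genus changes; depth and group size were not varied. In the smallest library a count of 0 allows a share of up to 0.0353%.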

Other observations

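Chosen only after the result was seen were the tests of depth and of the OVX state for richness the tests on ASV_70 and the test of fixed proportions, and the comparison of the 4 OVX groups with Sham was added after the data were seen.

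Against Sham, the 20 libraries of the 4 OVX groups held a lower share of Lachnospiraceae, 15.9% ± 9.79 against 33.4% ± 8.71 (exact permutation p = 0.0020, adjusted p = 0.0224 over 11 lists). Of the 20, 17 lay below the lowest Sham library. Butyrate producers, chiefly Kineothrix and Eubacterium by total count, averaged 7.42% ± 4.80 against 14.7% ± 6.60, and trimethylamine-forming genera, chiefly Lachnoclostridium, 3.56% ± 3.81 against 8.84% ± 3.67, with 15 and 16 of 20 libraries below the lowest Sham library (adjusted exact p = 0.0403 for both). Lachnoclostridium and Kineothrix are themselves Lachnospiraceae, so these lists overlap. In the edgeR fit of this comparison, Lachnoclostridium, Kineothrix and Eubacterium had adjusted p-values of 0.378, 0.384 and 0.936. Shares are parts of a whole, and Duncaniella and Ligilactobacillus averaged 24.7% and 23.6% against 13.2% and 11.9% in Sham. The lower shares of these lists therefore do not show a loss of the bacteria themselves. Lactic acid bacteria averaged 24.1% ± 11.6 against 12.04% ± 6.51 (adjusted exact p = 0.101), and the other 7 lists had adjusted exact p-values of 0.243 to 0.603. Expected ASVs averaged 235 ± 52.6 against 358 ± 35.1 (exact permutation p = 4e-05), the Shannon index 4.23 ± 0.365 against 4.91 ± 0.156 (exact permutation p = 0.00036), and R2 was 0.119 (exact permutation p = 0.0012). These p-values treat the 20 libraries as exchangeable with Sham; with the 5 groups as units the smallest possible p is 0.20.

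Lawsonibacter was the 1 genus past the threshold in the edgeR fit of this comparison, at 1.56% ± 0.920 against 0.333% ± 0.201 (log2 fold change 2.88, SE 0.68, adjusted p = 0.0176), with 15 of 20 libraries above the highest Sham library. The call was lost without Sham replicate 1, 2 or 5, where edgeR called 0 genera. Of 100 splits of the 25 libraries, the real one included, 35 gave at least 1 genus, and the highest other split gave 4. Chance can therefore not be excluded for this call. At an unadjusted edgeR p under 0.05 there were 16 genera, where other splits gave a median of 7 and at most 17. Of the 100 splits, the real one included, 2 gave at least 16. Marvinbryantia, chosen after its values were seen, held 0.177% ± 0.204 against 0.937% ± 0.507, with 16 of 20 libraries below the lowest Sham library (edgeR adjusted p = 0.0908).

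Fewer ASVs were found in OVX than in Sham. Depth is argued against as the whole cause. Among libraries with totals under 12000 (3 Sham, 5 OVX) the difference in expected ASVs was -86.8 (SE 19.9, exact permutation p = 0.0357). Over all libraries of both groups it was -105.6, so a part due to depth is not excluded. Reads taken up by Duncaniella and Ligilactobacillus are argued against as the whole cause, since without these genera it was -80.6 (SE 16.1, exact permutation p = 0.00794). Gene copies or sequence errors counted as ASVs are argued against as the whole cause too. Species names differed by -15.5 (86.4 ± 4.26 in OVX and 102 ± 5.70 in Sham, exact permutation p = 0.00794). Copies may carry several such names, since these are names of relatives, so that count alone cannot decide. A count of genera, not planned beforehand, differed by -7.62 (60.5 ± 2.43 in OVX and 68.1 ± 2.27 in Sham, exact permutation p = 0.00794). The OVX state may be the source, as all 4 OVX groups had lower means than Sham, the highest being 252.3, with exact p-values of 0.00794 to 0.0159. It cannot be told apart from a difference in cage, litter or day between Sham and the rest, which the labels do not give.

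The 6 most abundant ASVs assigned to Ligilactobacillus murinus held 19.95% of all counts and kept nearly fixed proportions in all 25 libraries, with means of 14.3% to 19.4% of their sum and SDs of 0.87 to 1.5 points. A candidate explanation is that they are copies of the 16S gene in 1 genome. Their chi-square against fixed proportions was 1.57 per degree of freedom over 120 degrees of freedom. Fixed proportions with counting error alone give 1, so some further spread remained. The 6 were singled out because their counts were seen to rise and fall together, so this value does not decide whether they are copies or separate strains. The pattern was not particular to this species. Duncaniella ASV_7, ASV_8, ASV_10 and ASV_12, a set that left out ASV_1, held 11.73% of all counts and gave 1.99 per degree of freedom. Of these, ASV_12 was named Duncaniella freteri and the others Duncaniella dubosii. No biological explanation was tested.

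A further such variant, ASV_70, made up 1.33% ± 0.163 of the counts of itself and these 6 ASVs in OVX, 1.12% ± 0.421 in OVX+GEX and 1.07% ± 0.620 in OVX+FMT, and was seen in 5, 5 and 4 of 5 libraries. In OVX+PBS it had 0 counts beside 8459 of the 6, which allows a share of up to 0.0355%. In Sham it was seen in 2 of 5 libraries, at a mean of 0.51% ± 0.706. The exact permutation p was 0.00794 for OVX+PBS against OVX and 0.0476 for OVX+FMT against OVX+PBS. For OVX against Sham the exact permutation p was 0.032, and for OVX+GEX against OVX 0.286. The variant was singled out from 379 after its values were seen.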
